A study of Homo sapiens with 10 samples.

How the data were processed

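RNA of 10 ocular tissues was analysed on the gene-level version of the Affymetrix Human Exon 1.0 ST array, 1 array per tissue. Per the labels, donor eyes were held cold in RNALater until the tissues were dissected, total RNA was extracted, and RNA from 6 donors was pooled for each tissue. The protocol speaks of 20 donors in all, and whether the same 6 donors gave every tissue is not settled in the sources used here. Per the labels, SPIA-amplified cDNA was fragmented and labelled with biotin.

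The deposited values are gene-level intensities on a linear scale, 1 per transcript cluster, for 22011 clusters. The submitters' processing notes name Affymetrix Power Tools, PLIER and the genome build hg18, with no version, role or order. Whether and how arrays were normalized to each other is not given in the sources used here. Values ran from 0.0001 to 26723 with array medians of 31.2 to 38.8, so they were read as linear and not as log2 values. No detection calls were used, and PLIER can return values close to 0 for dim genes. The number of arrays, 1 per tissue, limits the precision of every value.

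Clusters were named through the platform's annotation. Of the 22011 clusters, 16840 were listed there, 14432 with 1 gene symbol and 2408 with several, and 5171 were unnamed here. Of the 14432, 14404 were found by Entrez identifier in a reference gene table of assembly GRCh38.p14, which changed 0 symbols. No coordinates are printed, because that assembly differs from the hg18 named by the submitters. Only clusters with 1 symbol were used. XIST and Y-linked genes (9 clusters) were left out, since they say something about individual donors and nothing about tissues. For 197 genes with more than 1 cluster, the cluster with the highest mean over the arrays stood for the gene, which left 14223 genes. No value column was unmapped.

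Values were analysed as log2(intensity + 16) with the between-array scale as deposited. A gene was called tissue-enriched when its value was at or above the median of all genes on that array and at least 2-fold above the highest of the other 9 tissues. Of the 45 pairs of tissues, 6 neighbouring pairs were compared, and a gene counted when it differed at least 4-fold with the higher value at or above its array's median. These are rules of size and not tests. Fold changes on this scale understate the change of low genes. Similarity was described by Pearson and Spearman correlations across genes and by average-linkage clustering on 1 minus Pearson's r. The robust SD (scaled median absolute deviation) of the differences between the most similar pair of tissues served as a guide to the spread between single libraries. It holds both technical and biological differences and is not a replicate error. It was the lowest robust SD of the 45 pairs, which reached 0.41 for lens and iris, so it is an upper guide for the chosen pair only.

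There were 35 lists of marker genes, 24 with an expected tissue and 11 without. The lists for retina were rod photoreceptor, cone photoreceptor, bipolar cell, amacrine and horizontal cell, retinal ganglion cell and Müller glia. Those for RPE/choroid were retinal pigment epithelium, melanocyte and pigment, vascular endothelium and complement. Lens had crystallins and lens fiber and membrane genes, and cornea had corneal epithelium, keratocyte, corneal endothelium and corneal dystrophy genes. The rest were trabecular meshwork genes, ciliary epithelium and ion and bicarbonate transport for ciliary body, smooth muscle for iris, fibrous extracellular matrix and cartilage matrix for sclera, myelin and oligodendrocyte for optic nerve, and astrocyte for optic nerve head. Lists without an expected tissue covered conjunctival epithelium and goblet cells, skeletal muscle, Schwann cells, macrophages and microglia, T, B and plasma cells, mast cells, erythrocytes, adipocytes, immediate early and heat shock genes, eye transcription factors and glaucoma associated genes. A list was described by the count of members highest in the tissue, the count enriched, and the median over members of the tissue's value minus the median of the other 9 tissues. That median was placed among 10000 random lists of the same size, drawn with seed 1 and matched in 20 bins of mean expression; the percentile describes these libraries and is no test. Some genes belong to more than 1 list.

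The genes named were chosen by rule. They are the 10 tissue-enriched genes with the largest difference from the next tissue, or all where fewer were called. From each list with an expected tissue they are the 4 members with the largest difference from the median of the other tissues, and the members highest elsewhere where these were 5 or fewer. For each pair of tissues they are the 6 genes with the largest difference in each direction. From lists without an expected tissue they are the 3 members with the highest value in the tissue with the highest list mean, and any eye transcription factor or glaucoma gene. Photoreceptor genes named with RPE/choroid, the fall of a gene in further tissues, and all genes in the other observations were picked after their values were seen. The design, the lists, the rule and most of the other settings were fixed before the data were examined.

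The calling rule was tested on simulated data. Genes were planted at known folds over the other tissues, 500 of each size among 14223 genes, for the count of tissue-enriched genes over all tissues. Only genes with a base level at or above the median were planted. The other tissues shared the base level of the gene. At the 2-fold limit itself 13.6% were recovered, at 3-fold 85.2%, at 4-fold 97.4% and at 8-fold 99.8%. These rates describe such planted genes only. Recovery of dim genes, and of genes shared with a neighbouring tissue, was not tested. In 20 further sets drawn with the spread between optic nerve and optic nerve head and no difference, the highest number of genes called for any tissue was 16.

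Alternatives were a pseudocount of 1 or 64, quantile normalization of the 10 arrays, centring each array on its median, the mean of all clusters of a gene, no filter or a filter at the 75th percentile, a 4-fold rule, leaving a neighbouring tissue out, other list summaries and Spearman's rho. Clusters with several symbols or none were left out of all named results. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.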

Results

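Gene expression was measured in 10 dissected tissues of the human eye: lens, iris, ciliary body, trabecular meshwork, cornea, retina, retinal pigment epithelium with choroid (RPE/choroid), sclera, optic nerve head and optic nerve. Each tissue was represented by 1 exon array, hybridized with RNA pooled from 6 donors. The tissues therefore had no replicates, and no error or p-value could be given for any difference; every statement describes these 10 libraries. The question addressed was which genes mark each ocular tissue and how neighbouring tissues differ. The median intensity of an array ran from 31.2 in iris to 38.8 in optic nerve head. After combining probes into genes, 14223 genes were compared. Folds are ratios of intensity plus 16, which understate differences of dim genes. Many genes lay near the array median, where signal and background are hard to separate, so a low value does not show that a gene was silent.

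The optic nerve and the optic nerve head were the most alike of the 45 pairs of tissues, with a Pearson correlation across genes of 0.953 (Spearman 0.932). Ciliary body lay closest to RPE/choroid (0.903) and nearly as close to iris (0.901), 3 tissues that hold pigmented cells. Trabecular meshwork correlated at 0.869 with sclera and at 0.875 with RPE/choroid. Retina stood farthest from the rest, with a mean correlation of 0.708 with the other 9 tissues, followed by lens at 0.740 and cornea at 0.750. The least similar pair was iris and retina at 0.653. In average-linkage clustering, both optic nerve samples paired first, ciliary body joined RPE/choroid and then iris, trabecular meshwork joined sclera, and cornea, lens and finally retina came in last. Genes are not independent replicates, so these correlations carry no test.

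**Figure D1:**
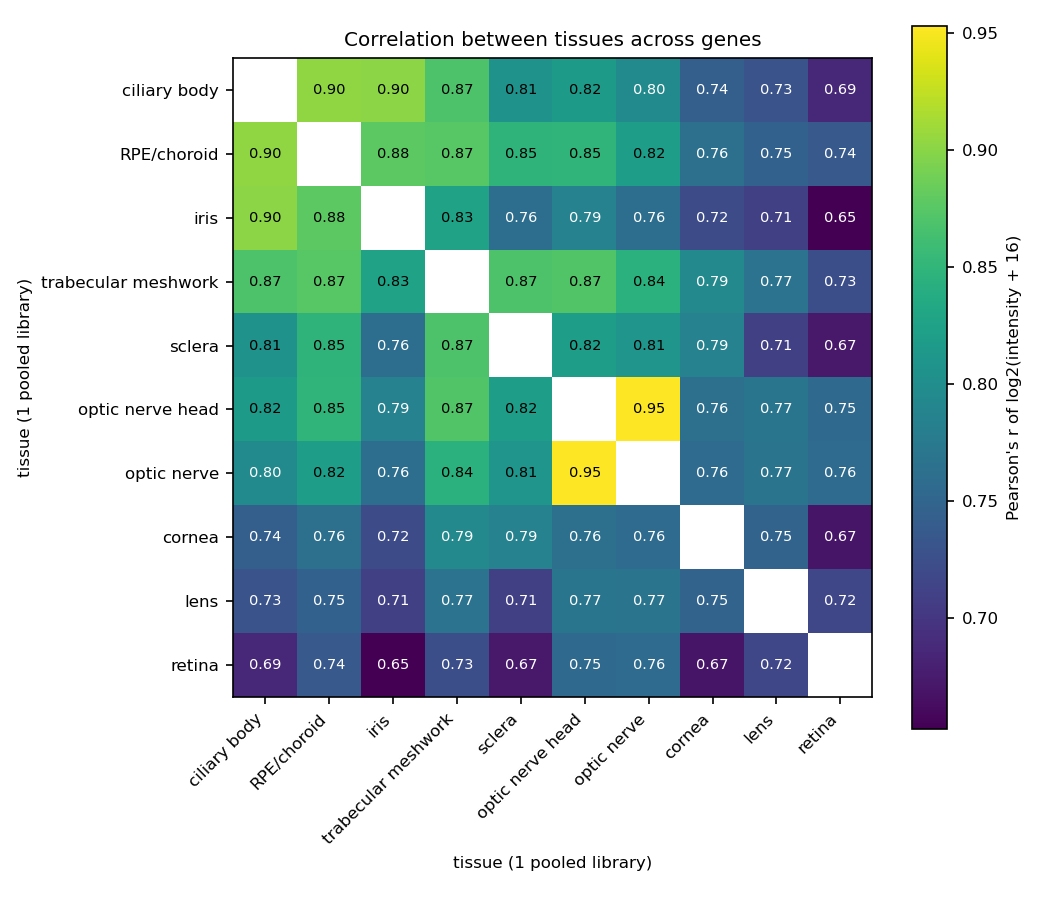
Pearson's r of log2(intensity + 16) across 14223 genes for each pair of the 10 tissues, 1 pooled library each, with tissues on both axes and r as the color and the printed number. Optic nerve and optic nerve head reached 0.95, and retina had the lowest values, down to 0.65 with iris.

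Lens, retina and cornea carried most of the tissue-enriched genes, defined as genes at or above the array's median and at least 2-fold above the highest of the other 9 tissues. Of 598 such genes, 247 belonged to lens, 110 to retina, 89 to cornea, 52 to trabecular meshwork, 39 to iris, 23 to sclera, 21 to RPE/choroid, 10 to ciliary body, 4 to optic nerve head and 3 to optic nerve. The optic nerve and head shared so many genes that leaving out the partner raised their counts to 63 for optic nerve and 85 for optic nerve head. Leaving out ciliary body raised iris to 59, leaving out iris raised ciliary body to 16, and leaving out retina raised RPE/choroid to 33. Quantile normalization lowered the lens count to 154 and the trabecular meshwork count to 30, and raised sclera to 39. Counts also depended on the pseudocount; at 64 in place of 16 they were 150 for lens, 71 for retina, 24 for trabecular meshwork, 17 for iris and 13 for RPE/choroid, and at 1 RPE/choroid had 36. Differences between optic nerve and optic nerve head served as a guide to the spread between single libraries, and as an upper guide for this pair only. Their robust SD was 0.23 on the log2 scale, the lowest of the 45 pairs, and 0.689% of genes differed by 2-fold or more. In 20 simulated sets with the spread of this pair and no tissue difference, calls per tissue averaged 7.7. They reached 15 for ciliary body, 12 for optic nerve head and 13 for optic nerve, above the observed counts of these 3 tissues. Each gene had 1 level in all simulated tissues, unlike the data, and the spread also holds biological differences of the pair. The sets therefore cannot decide whether these calls were chance.

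**Figure D2:**
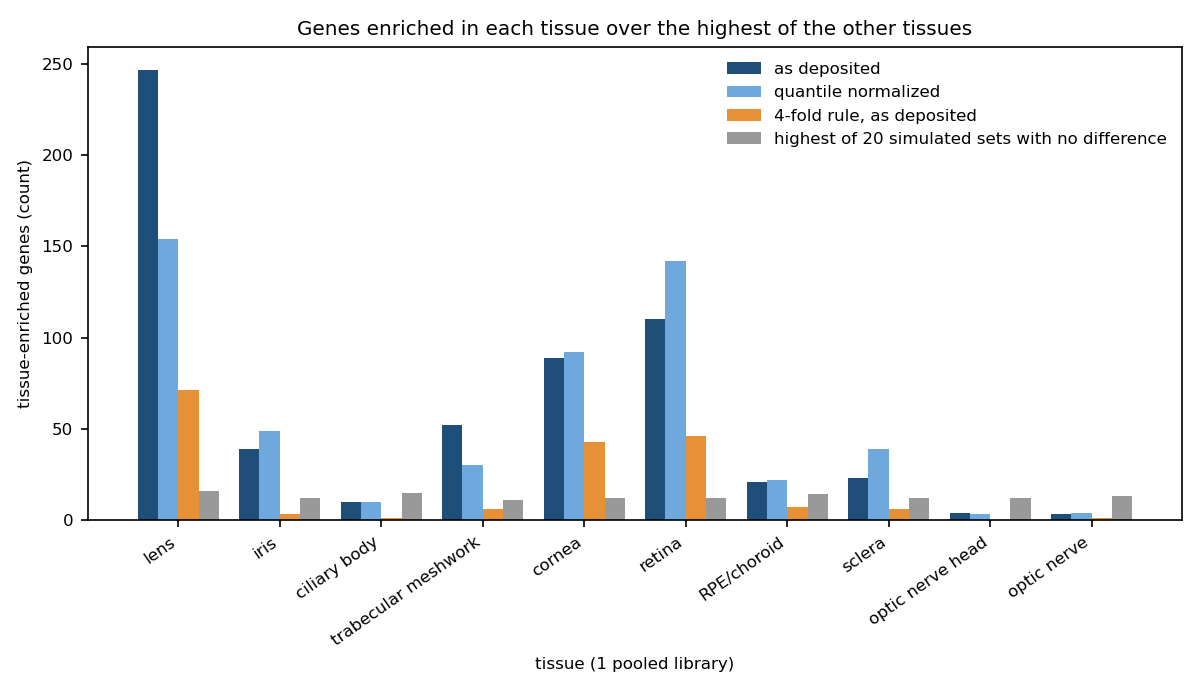
Number of tissue-enriched genes per tissue (count) as deposited, after quantile normalization and under a 4-fold rule, with the highest count of 20 simulated sets without any difference. Lens had 247 genes as deposited and 154 after quantile normalization, while optic nerve head and optic nerve had 4 and 3.

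The retina was marked by photoreceptor genes. Its highest-ranking gene was PPEF2 (transcript cluster 2773823), a photoreceptor phosphatase, at 1326 and 26.1-fold above the next tissue. PDE6A, the catalytic subunit of the rod phosphodiesterase, followed at 909 (17.4-fold) and PRPH2, which shapes the outer segment disc rim, at 1028 (16.6-fold). The other leading genes were ANO2 (14.2-fold), SAMD7 (12.6-fold), RP1 (12.6-fold), PROM1 (11.4-fold), CPLX4 (11.4-fold), SAG (11.4-fold) and IMPG2 (10.1-fold). In 49 of the 110 retina-enriched genes the next tissue was RPE/choroid.

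Of 22 measured rod genes, 21 were highest in retina and 16 were enriched there, with a median difference of 3.23 (log2) from the median of the other tissues. The median exceeded those of all 10000 random lists of matched size and expression, which describes these libraries only. SAG, the rod arrestin, reached 2669 (40.1-fold over the median of the other tissues), RCVRN, the calcium sensor recoverin, 3989.6 (38.4-fold) and CNGA1, the rod cyclic nucleotide channel, 1426 (27.5-fold). The exception was the rod transcription factor NR2E3, at 38.2 in retina and 38.6 in sclera. The cone list behaved alike, with 7 of 11 members highest in retina, 6 enriched and a median of 2.03, above all random lists. PDE6H of the cone phosphodiesterase was at 5396 (69.5-fold), GUCA1C at 605 (19.7-fold), GNGT2 at 381 (10.5-fold) and GNAT2, the cone transducin, at 339 (8.14-fold). CNGB3 was higher in RPE/choroid (105) than in retina (61.6), while CNGA3, THRB and KCNV2 were highest in iris, lens and trabecular meshwork at no more than 84.6.

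Neurons of the inner retina gave smaller differences. The bipolar list had 5 of 10 members highest in retina, 1 enriched and a median of 0.42, above all random lists; the enriched gene was CABP5, a calcium-binding protein, at 539. GRIK1 was at 61.9 and OTX2 at 68.6, whereas PRKCA was at 68.4 in retina and 94.7 in optic nerve. GRM6, PCP2, LHX4 and NYX were likewise highest outside the retina, at 69.4 or less. Among amacrine and horizontal cell genes, 6 of 15 were highest in retina and 1 was enriched, with a median of 0.34 at percentile 99.99 of the random lists. The calcium-binding proteins CALB1 (306), PVALB (148) and CALB2 (55.0) led that list, followed by TFAP2B at 46.9, which was higher in cornea (97.1) and trabecular meshwork (92.7). Retinal ganglion cell genes were highest in retina for 6 of 13 members, 4 of them enriched, with a median of 0.26 at percentile 99.92. The neurofilament genes NEFM (489), NEFL (87.2) and NEFH (2.70-fold over the median of the other tissues) and STMN2 (140) made up the 4 enriched members.

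Genes of Müller glia, the radial glia of the retina, were not confined to it. Only 2 of 10 members were highest in retina and 0 were enriched, although the median difference of 1.01 exceeded all random lists. The list mean was higher in optic nerve head (8.13) than in retina (7.72), the mean of log2 values being taken over members. WIF1, a secreted Wnt inhibitor, was at 388 in retina and 463 in optic nerve head, SLC1A3, a glial glutamate transporter, at 199 and 615, and FRZB at 515 in retina against 939 in ciliary body. CRYM was highest in retina at 163.

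RPE/choroid had some genes of the pigment epithelium among its leading genes, while pigment and vascular genes were shared with other tissues. Its leading gene was S100A12 (cluster 2435981), a calcium-binding protein of neutrophils, at 670 and 14.2-fold above the next tissue, and S100A8, of the same family, reached 897 (5.79-fold). RPE65, the isomerase of the visual cycle, was at 735 (6.38-fold), and TTR, which carries retinol-binding protein and thyroid hormone, at 2571 (4.81-fold). CLTRN (5.68-fold), ALKAL2 (4.47-fold), CLIC6 (4.00-fold), EGFL6 (3.38-fold), the chemokine CXCL9 (3.25-fold) and TSPAN8 (779 against 249 in ciliary body) completed the 10 leading genes.

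Within the pigment epithelium list, 9 of 16 members were highest in RPE/choroid and 3 were enriched, with a median of 0.90 above all random lists. RGR, a retinal G protein-coupled receptor, was at 880.3 (22.3-fold over the median of the other tissues) and RDH10, a retinol dehydrogenase, at 433 (3.83-fold). Of 7 measured melanocyte and pigment genes, 4 were highest in RPE/choroid and 0 were enriched there, with a median of 0.53 at percentile 99.94. The list mean was higher in iris (7.64) than in RPE/choroid (7.46). TYRP1, a melanin synthesis enzyme, was at 1127 in RPE/choroid, 851 in iris and 653 in ciliary body, and PMEL at 356 and 289 in RPE/choroid and iris. MLANA reached 1189 in iris against 490 in RPE/choroid, SLC45A2 was also highest in iris (119), GPR143 was highest in sclera (48.5) and RAB38 was at 78.8 in RPE/choroid.

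The vascular endothelium list had 3 of 13 members highest in RPE/choroid and 4 in sclera, 0 enriched in RPE/choroid and a median of 0.30 at percentile 99.97. EMCN was at 120 in RPE/choroid and 123.1 in iris, PECAM1 at 118, FLT1 at 127 and TEK at 37.1. Complement genes had a median of 0.25 in RPE/choroid at percentile 97.3, with 1 of 10 highest there and 0 enriched. Their mean was highest in ciliary body (7.20), followed by optic nerve head (7.16). CFI was at 312 in RPE/choroid and 310 in ciliary body, CFB at 427 and 798, CFD at 231 in RPE/choroid against 364 in sclera, and C3 at 151 in RPE/choroid against 173 in optic nerve head.

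Retina and RPE/choroid differed 4-fold in 275 genes, of which 72 were higher in retina and 203 in RPE/choroid. The total was 512 at a pseudocount of 1 and 100 at 64, with more genes higher in RPE/choroid in each case. Genes higher in retina were led by PPEF2 (28.8-fold), PRPH2 (21.9-fold), PDE6A (17.4-fold), ANO2 (14.5-fold), SAMD7 (14.4-fold) and RP1 (12.6-fold). Those higher in RPE/choroid included the lipocalin APOD (1214, 68.5-fold), the phospholipase PLA2G2A (983, 41.9-fold), the protease inhibitor SLPI (722, 39.8-fold), the hemoglobin gene HBB (1034, 37.0-fold), TYRP1 (34.2-fold) and the matrix gene MGP (1357, 33.3-fold). Photoreceptor transcripts were still seen in RPE/choroid, with RCVRN at 536, GNGT1 at 528 and PDE6H at 1007. For the 22 retina-enriched rod and cone genes, the median share of the retinal signal found in RPE/choroid was 5.13% (quartiles 2.30% and 12.3%). Only genes at least 2-fold above every other tissue entered this share, which limits it by construction. Genes with more signal in RPE/choroid were left out, such as CNGB3, at 105 there and 61.6 in retina.

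Lens gave the largest differences in the series, and its strongest genes were crystallins, the structural proteins of the lens. CRYBA4 (cluster 3941076) reached 26723, the highest value on any array, against 25.9 in the next tissue, a 638-fold difference. CRYBA2 was at 10438 (137-fold), CRYAA at 12801 (81.6-fold), CRYBA1 at 3636 (97.3-fold), CRYBB1 at 3671 (53.3-fold) and CRYGD at 1599.6 (75.2-fold). Of 12 crystallins, 11 were highest in lens and 9 were enriched, with a median difference of 5.52 above all random lists. The exception was CRYGN, at 43.9 in lens and 58.7 in optic nerve head.

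Genes of lens fiber cells followed the crystallins. The beaded filament genes BFSP1 (6038, 128-fold above the next tissue) and BFSP2 (3698, 81.9-fold) and LGSN (2147, 55.2-fold) were among the 10 leading lens genes, together with OR4A16 of the olfactory receptor family (2013, 37.1-fold). In the lens fiber and membrane list, 10 of 13 members were highest in lens and 8 were enriched, with a median of 2.36 above all random lists. PROX1, a transcription factor of fiber cell differentiation, was at 438 (18.5-fold over the median of the other tissues). GJA3, PITX3 and DNASE2B were highest in sclera (85.8), cornea (109) and ciliary body (22.1).

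Cornea was marked by genes of its epithelium and by KERA of its stroma. The leading genes were the keratins KRT24 (cluster 3756416; 8435, 145-fold above the next tissue) and KRT12 (5396, 113-fold), the desmosomal cadherins DSG1 (3918, 120-fold), DSC3 (2253, 61.8-fold) and DSG3 (815, 24.0-fold), and the stromal proteoglycan KERA (6590.3, 118-fold). SCEL (60.7-fold), MAL2 (50.4-fold), ALDH3A1, the abundant corneal aldehyde dehydrogenase (3768, 37.3-fold), and UPK1B (25.2-fold) completed the group. All 15 measured corneal epithelium genes were highest in cornea and 13 were enriched, with a median of 3.37 above all random lists; KRT14, a basal keratin, was at 2287.

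Keratocyte genes split mainly between cornea and sclera. In cornea, 6 of 12 were highest and 3 enriched, with a median of 1.71 above all random lists. Of the others, 3 were highest in sclera, 2 in lens and 1 in ciliary body. LUM, a stromal proteoglycan, was at 538 in cornea and 157 in sclera, whereas ANGPTL7 was at 836 in cornea, 815 in trabecular meshwork and 1619 in sclera. Genes of the corneal endothelium did not mark the cornea. Of 9 members 1 was highest there and 0 were enriched, and the median of 0.011 lay at percentile 45.5; it was -0.13 after quantile normalization and -0.033 after median centring. COL8A1 was at 67.5, SLC4A4 at 109, SLC4A11 at 76.6 and CA3 at 35.4 in cornea. Among genes of corneal dystrophies, 4 of 10 were highest in cornea and 2 were enriched, with a median of 0.22 at percentile 94.1. TGFBI, mutated in stromal dystrophies, reached 1402 in cornea against 103 in trabecular meshwork, and DCN was at 1509 in cornea and 1279 in sclera.

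Cornea and sclera, the continuous outer coat of the eye, differed 4-fold in 163 genes, 91 higher in cornea and 72 in sclera. The split turned to 88 and 105 after quantile normalization and to 161 and 183 at a pseudocount of 1, and the total was 75 at a pseudocount of 64. Cornea was higher for KRT24 (159-fold), DSG1 (142-fold), KERA (118-fold), KRT12 (113-fold), MAL2 (63.6-fold) and DSC3 (61.8-fold). Sclera was higher for the growth factor PTN (1432, 38.9-fold), HBB (702, 37.3-fold), SCGB3A2 (27.5-fold), SLPI (1942, 26.2-fold), PI16 (984) and S100B (529, 22.9-fold).

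The trabecular meshwork library was led by contractile genes of muscle. MYL9 (cluster 3883921), a myosin light chain, was at 1814 against 201 in ciliary body (8.45-fold), and MYH11, the smooth muscle myosin heavy chain, at 2346 against 632 (3.64-fold). CASQ2 (657, 7.95-fold) and ATP2A1 (446, 6.53-fold) belong to the calcium store of muscle cells, and MYOM1 (4.36-fold) and CNN1 (3.21-fold) to the contractile apparatus. GNG7 (4.35-fold), GUCY1A1, a nitric oxide receptor subunit (4.31-fold), RSPO2 (3.81-fold) and the calcium release channel ITPR1 (3.21-fold) were the remaining leading genes. For 30 of the 52 enriched genes, the next tissue was ciliary body.

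Smooth muscle genes had been assigned to iris, which holds the pupillary muscles, but 0 of 13 were highest there and 0 were enriched. Their median in iris was 0.029 at percentile 95.3 and rose to 0.27 after quantile normalization; MYH11 was at 275, PLN at 156, KCNMB1 at 36.4 and LMOD1 at 150 in iris. In trabecular meshwork 11 of the 13 were highest and 5 were enriched, and 8 were highest after quantile normalization. The list mean was 7.71 in trabecular meshwork, 6.72 in ciliary body and 6.32 in iris.

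Genes known from trabecular meshwork were shared with other tissues, most of all with sclera. Of 14 members, 5 were highest in trabecular meshwork and 0 were enriched, although the median of 1.20 exceeded all random lists. MYOC, the glaucoma gene myocilin, was at 1575 in trabecular meshwork and 1006 in sclera, and CHI3L1 at 777 and 741. RARRES1 was at 332 in trabecular meshwork and 835 in iris. The list mean was 7.95 in trabecular meshwork and 7.69 in sclera, followed by 7.37 in RPE/choroid and 7.31 in both ciliary body and iris.

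Trabecular meshwork and ciliary body differed 4-fold in 69 genes, 44 higher in trabecular meshwork and 25 in ciliary body. This split depended on the scale of the arrays, with 28 and 39 after quantile normalization and 37 and 33 after median centring, and the total was 159 at a pseudocount of 1 and 18 at 64. ANGPTL7 (20.4-fold), MYL9 (8.45-fold), CASQ2 (7.95-fold), the hyaluronan-binding CEMIP (256, 7.54-fold), EIF3L (225, 6.86-fold) and the glycolytic enzyme ENO1 (255, 6.78-fold) were higher in trabecular meshwork. In ciliary body EIF3L (19.2) and ENO1 (24.0) lay under the array median of 34.0. Whether tissue or measurement caused these low values was not tested. ERICH5 (755, 25.1-fold), TFPI2 (700.2, 17.9-fold), SCG5 (759, 15.7-fold), PRG4 (369, 13.6-fold), CCL20 (376, 11.3-fold) and the transcription factor PAX6 (424 against 26.9, 10.2-fold) were higher in ciliary body.

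Against sclera, trabecular meshwork was higher for 75 genes and lower for 21, and after quantile normalization for 61 and 35; the total was 165 at a pseudocount of 1 and 34 at 64. The genes higher in trabecular meshwork were MYH11 (31.1-fold), PCP4 (3364, 21.5-fold), PLCB4 (1132, 19.0-fold), CDH6 (416, 14.5-fold), RGS2 (2625, 13.6-fold) and CSRP2 (414, 13.6-fold). Those higher in sclera were SCGB3A2 (26.5-fold), THBS4 (959, 26.5-fold), SLPI (25.2-fold), DPT (20.7-fold), PI16 (10.5-fold) and HBB (9.32-fold).

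Ciliary body had few genes of its own and resembled its neighbours. SLC35G1 (cluster 3258772) was at 183 against 33.0 in iris (4.06-fold), followed by CHRDL2 (141, 3.50-fold), SLC9B2 (204, 2.74-fold), the coagulation factor F5 (233, 2.27-fold) and SLC38A11 (196, 2.26-fold). CCL20 (2.19-fold), opticin, OPTC (239, 2.15-fold), the neuroendocrine chaperone SCG5 (2.08-fold), TAS2R5 (41.8, 2.02-fold) and FGFBP2 (166, 2.01-fold) lay just above the 2-fold limit. SCG5 fell under it after median centring (0.97 on the log2 scale), and FGFBP2 after median centring (0.93) and quantile normalization (0.95). At a pseudocount of 64 only SLC35G1, CHRDL2 and SLC9B2 of the 10 passed it.

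Of 15 ciliary epithelium genes, 6 were highest in ciliary body and 1 was enriched, with a median of 0.33 above all random lists. Their mean was 6.70 in ciliary body and 6.69 in optic nerve head, an order that turned at a pseudocount of 64. OPTC led the list, ceruloplasmin, CP, was at 793, ZIC1 at 175 against 511 in optic nerve head, and TRPM3 at 122 against 375 in lens. Ion and bicarbonate transport genes, which serve the secretion of aqueous humor, were not set apart in ciliary body. Of 13 members 1 was highest there, the bicarbonate transporter SLC4A4 at 163, and 0 were enriched, with a median of 0.071 at percentile 91.1. ATP1B3 was at 172, CA14 at 39.7 and AQP1 at 110 in ciliary body, and the list mean was highest in optic nerve head.

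Iris was led by LINC00314 (cluster 3916964; 376, 9.11-fold above the next tissue) and by IL13RA2, the decoy receptor of interleukin 13 (459, 6.09-fold). HPDL (137, 4.33-fold), TMEM100 (207, 3.68-fold), RASSF9 (332, 3.46-fold), MROH9 (85.7, 3.17-fold), CHST9 (136, 3.09-fold), TFEC, a relative of the pigment cell factor MITF (89.3, 2.92-fold), QPCT (561, 2.74-fold) and TMEM161B (197, 2.69-fold) followed; MROH9 and TFEC fell under the 2-fold limit at a pseudocount of 64. The next tissue was ciliary body for 15 of the 39 iris genes and RPE/choroid for 12. Both scalings raised the median of all genes in iris by 0.14 (log2), the only tissue where the shift exceeded 0.1.

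Ciliary body and iris differed 4-fold in 39 genes, 20 higher in ciliary body and 19 in iris, and 14 and 21 after median centring. The total was 92 at a pseudocount of 1 and 7 at 64. PRG4, lubricin (12.2-fold), ASB11 (232, 9.94-fold), IK (1036 against 112, 8.23-fold), the growth cone gene GAP43 (183, 7.05-fold), TSPAN8 (249, 5.54-fold) and CSRP2 (106, 5.30-fold) were higher in ciliary body. LINC00314 (12.6-fold), SUDS3 (469 against 35.1, 9.49-fold), RASSF9 (7.92-fold), SCGB1D2 (113, 6.28-fold), TMEM100 (6.14-fold) and IL13RA2 (6.09-fold) were higher in iris. For IK and SUDS3, whether tissue or measurement caused the low value was not tested.

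Sclera expressed genes of connective tissue, together with SCGB3A2 (cluster 2834472), a secretoglobin at 767 and 12.4-fold above the next tissue. DPT, the matrix protein dermatopontin (626, 10.96-fold), PI16 (984, 7.04-fold), MKX, a tendon transcription factor (158, 4.77-fold), CYTL1 (493, 4.15-fold) and the proteoglycan PRELP (1038, 4.01-fold) followed. The protease MMP3 (728, 3.29-fold), PLA2G2A (3021, 3.04-fold), MYO1D (202, 2.98-fold) and the protease inhibitor TIMP3 (1009, 2.94-fold) completed the 10 leading genes. Fibrous matrix genes were highest in sclera for 11 of 21 members, with 3 enriched and a median of 0.74 above all random lists. THBS4 was at 959 (20.5-fold over the median of the other tissues), COL12A1 at 767 against 721 in cornea, and FMOD at 394 (7.14-fold). Cartilage matrix genes were highest in sclera for 6 of 12 members, with 0 enriched and a median of 0.33 above all random lists. COL11A1 was at 114 in sclera and 143 in optic nerve head, CHAD at 56.6, COMP at 40.1 and HAPLN1 at 23.8, near background.

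Optic nerve head and optic nerve shared the genes of myelin and astrocytes. MBP, the myelin basic protein, was at 2704 in optic nerve and 1883 in optic nerve head, and at no more than 113 elsewhere. CNDP1 was at 373 and 416, UGT8, an enzyme of myelin lipid synthesis, at 198 and 218, and TF, transferrin, at 313 and 323 against 441 in retina. Of 16 myelin and oligodendrocyte genes, 3 were highest in optic nerve and 0 enriched, with a median of 0.56 above all random lists, while 7 were highest in optic nerve head; after quantile normalization 7 were highest in optic nerve. The list mean was 7.07 in optic nerve and 7.001 in optic nerve head.

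Astrocyte genes had been assigned to optic nerve head. Of 12 members 3 were highest there and 0 enriched, with a median of 1.03 above all random lists, and 5 were highest in optic nerve. The water channel AQP4 was at 941 in optic nerve head and 1548 in optic nerve, the intermediate filament GFAP at 379 and 518, SLC1A3 at 615 and 576, and SLC1A2 at 127 and 159. The list mean was 7.78 in optic nerve head and 8.02 in optic nerve.

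Between optic nerve and optic nerve head 7 genes differed 4-fold, a count that was 24 at a pseudocount of 1 and 3 at 64. MT3, a metallothionein of the nervous system, was at 658 in optic nerve and 104 in optic nerve head (5.62-fold). The 6 genes higher in optic nerve head were TTR (429, 7.49-fold), WIF1 (463, 7.19-fold), CHI3L2 (191, 6.35-fold), CXCL14 (172, 6.13-fold), the endothelial gene ESM1 (190, 5.91-fold) and the cardiac actin ACTC1 (72.2, 4.43-fold). The genes enriched over all other tissues were MT3 (cluster 3662093), TAS2R39 (134, 2.56-fold) and GABRG1 (121, 2.34-fold) in optic nerve. In optic nerve head they were ESM1 (cluster 2856995, 2.55-fold), C7 (179, 2.26-fold), the axonal motor KIF5A (202, 2.23-fold) and GAP43 (411, 2.15-fold). GAP43 fell under the 2-fold limit after quantile normalization (0.89 on the log2 scale) and after median centring (0.98). At a pseudocount of 64 all 4 genes of optic nerve head fell under it, and in optic nerve only MT3 passed.

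Several lists of blood and immune cells, for which no tissue had been named, had their highest mean in RPE/choroid, but few of their members were highest there outside the macrophage list. Of 13 macrophage and microglia genes, 7 were highest there (list mean 6.93), among them CD163 at 336 and TYROBP at 322, whereas CD68 was at 222 in RPE/choroid and 394 in sclera. After quantile normalization 4 of the 13 were highest in RPE/choroid. The erythrocyte list had 1 of 5 members highest in RPE/choroid and 2 in retina, and its mean rested on HBB, at 1034 in RPE/choroid and 702 in sclera; the other members named by the rule, ALAS2 (31.6) and SLC4A1 (43.2), were near background. The T, B and plasma cell list had a mean of 5.69 in RPE/choroid, where 2 of 11 members were highest against 3 in retina, with JCHAIN of secreted antibodies at 105 and enriched, MS4A1 at 82.8 and CD8A at 40.9. In the mast cell list 2 of 4 members were highest in RPE/choroid; CPA3, a mast cell protease, was at 104 in RPE/choroid and enriched, KIT was at 63.7 there and 186 in cornea, and HDC was at 31.5. Immediate early and heat shock genes had their highest mean in RPE/choroid (6.77), followed by cornea (6.74), with 3 of 14 members highest in each. In RPE/choroid EGR1 was at 573, FOS at 323 and HSPH1 at 259.8, against 397 in lens for the last of these.

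Other cell types gave weaker patterns. The adipocyte list had its highest mean in ciliary body (6.49), where FABP4, a fatty acid carrier, was at 274, CFD at 236 and LPL at 153. Only 1 of its 7 members was highest there, against 4 in sclera, and the median difference in ciliary body was -0.051. Schwann cell genes had their highest mean in optic nerve (6.86), followed by trabecular meshwork (6.78), an order that turned at a pseudocount of 1. Only 1 of 5 members, S100B at 2184, was highest in optic nerve; PRX was at 74.9 there and 84.7 in cornea, and SOX10 at 60.0 there and 69.3 in RPE/choroid. Skeletal muscle genes had their highest mean in optic nerve head (6.00), where 3 of 19 members were highest and MYL1 was at 127, TNNC2 at 112 and NEB at 103. Trabecular meshwork and sclera each had 5 members highest, with NEB at 129 and ATP2A1 enriched in trabecular meshwork and TNNC2 at 119 in sclera. Conjunctival epithelium and goblet cell genes had their highest mean in cornea (6.17), with 5 of 10 members highest there; KRT13 was at 459.7, KRT19 at 80.6 and TFF3 at 61.7.

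**Figure D3:**
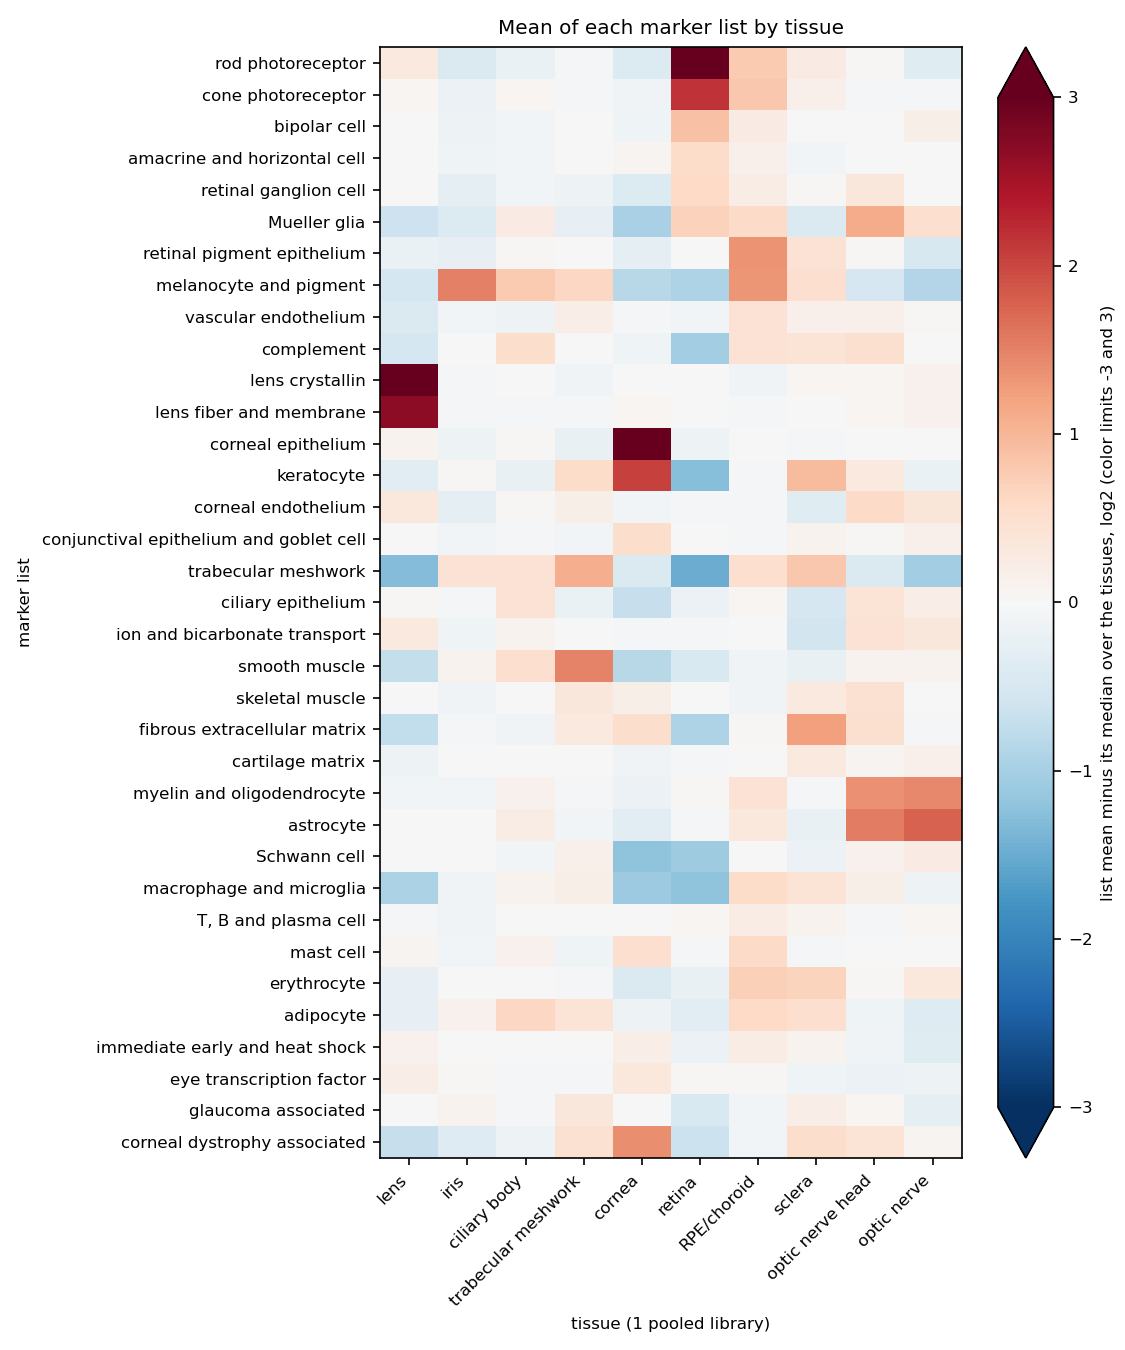
Mean of log2(intensity + 16) over the members of each of 35 marker lists, minus the list's median over the 10 tissues, with lists on the vertical axis, tissues on the horizontal axis and the difference as color limited to 3 on the log2 scale. Photoreceptor lists stand out in retina, crystallin and fiber lists in lens, corneal epithelium in cornea, smooth muscle in trabecular meshwork, and myelin and astrocyte lists in both optic nerve samples.

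Transcription factors of eye development were spread over the tissues, with the highest list mean in cornea (6.33) and 6 of 13 members highest there. PAX6 was at 1208 in cornea, 583 in lens, 437 in iris, 424 in ciliary body, 299 in retina and 147 in RPE/choroid, and at 49.5 or less in trabecular meshwork, sclera, optic nerve head and optic nerve. FOXC2 was at 199.6 and PITX3 at 109 in cornea, MAF at 223 in lens and MITF at 163 in RPE/choroid.

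Genes associated with glaucoma had their highest mean in trabecular meshwork (6.39), followed by sclera (6.26), an order that turned after quantile normalization. Of 17 measured members, 1 was highest in trabecular meshwork and 1 in retina. Cornea had 5, lens and optic nerve head 3 each, and iris and sclera 2 each. MYOC fell from 1575 there to 320 in iris and 2.92 in retina. CYP1B1, a cytochrome P450 mutated in congenital glaucoma, was at 303 in iris, 294 in ciliary body and 264 in trabecular meshwork, and at 5.16 in retina and 3.53 in cornea. OPTN, optineurin, was at 549 in lens and between 52.6 and 141 elsewhere, and CAV1, caveolin, at 284 in lens. LOXL1, the elastin cross-linking enzyme of exfoliation glaucoma, ranged only from 98.0 in iris to 180.4 in sclera, and TMCO1 from 119 in sclera to 225 in cornea. SIX6, CDKN2A, ASB10, ATOH7 and LMX1B stayed at or below 40.2 in every tissue.

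**Figure D4:**
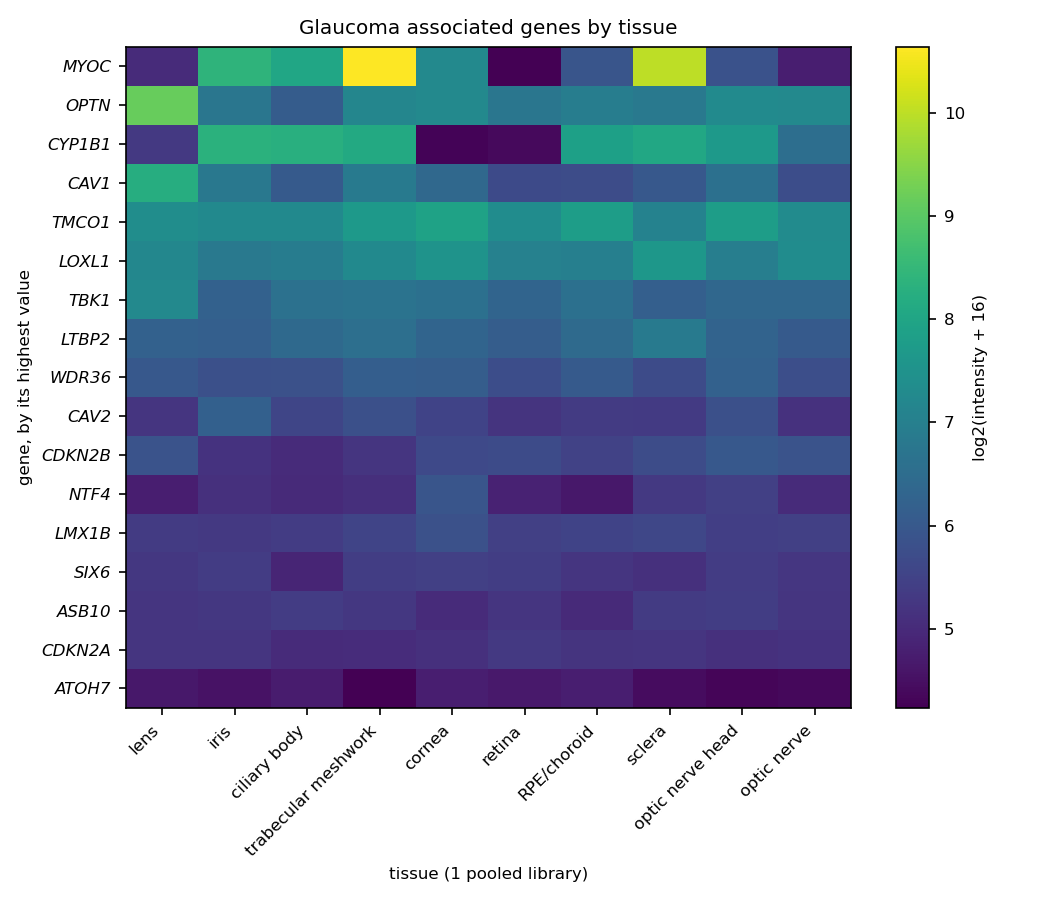
Log2(intensity + 16) of the 17 measured glaucoma associated genes (vertical axis, ordered by their highest value) in the 10 tissues (horizontal axis), as color. MYOC was brightest in trabecular meshwork at 1575 and sclera at 1006, OPTN in lens at 549, and CYP1B1 was dim in lens, cornea and retina.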

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

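The counts with lens left out of the other tissues were chosen after seeing the data. No paired analysis was possible because each tissue had 1 pooled library, and nothing in the labels ties a pool of one tissue to that of another. Except where the construction of an alternative shows it, the cause was not tested.

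The pair of optic nerve and optic nerve head was the most alike under all 7 alternatives for the correlation, from 0.932 with Spearman's rho to 0.959 at a pseudocount of 64; median centring cannot change Pearson's r. For tissue-enriched counts, 69 alternative values lay within 1.5 times the reported count and 29 did not. For pairs these numbers were 30 and 12. Of the list medians, 111 moved by less than the spread guide, 47 moved further, and 10 that lay above the guide changed sign. Another 6 sign changes came from medians below the guide, 3 of them for corneal endothelium, whose median was -0.13 after quantile normalization and -0.033 after median centring. Named genes passed their threshold in 415 cases and fell under it in 20, with 15 of these at a pseudocount of 64, 3 after median centring and 2 after quantile normalization; 0 changed direction.

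A larger pseudocount shrinks the fold of dim genes by construction. At a pseudocount of 64, tissue-enriched counts were 150 for lens, 17 for iris, 3 for ciliary body, 24 for trabecular meshwork, 71 for retina, 13 for RPE/choroid, 0 for optic nerve head and 1 for optic nerve. At a pseudocount of 1 they were 36 for RPE/choroid, 7 for optic nerve head and 5 for optic nerve. With pseudocounts of 1 and 64, the genes differing 4-fold numbered 24 and 3 between optic nerve and optic nerve head, 512 and 100 between retina and RPE/choroid, and 92 and 7 between ciliary body and iris. They numbered 159 and 18 between trabecular meshwork and ciliary body, 165 and 34 between trabecular meshwork and sclera, and 344 and 75 between cornea and sclera.

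After quantile normalization the counts were 154 for lens, 30 for trabecular meshwork and 39 for sclera. A 4-fold rule calls fewer genes by construction. It called 71 for lens, 3 for iris, 1 for ciliary body, 6 for trabecular meshwork, 43 for cornea, 46 for retina, 7 for RPE/choroid, 6 for sclera, 0 for optic nerve head and 1 for optic nerve. Leaving a neighbour out removes a competitor by construction. Iris had 59 genes without ciliary body, ciliary body 16 without iris, RPE/choroid 33 without retina, optic nerve head 85 without optic nerve, and optic nerve 63 without optic nerve head.

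List medians (log2) at a pseudocount of 1 were 3.75 for rod, 2.46 for cone, 1.28 for Müller glia, 5.91 for crystallin, 2.89 for lens fiber and 3.83 for corneal epithelium genes. At a pseudocount of 64 they were 2.61 for rod, 1.29 for cone, 0.66 for Müller glia, 0.66 for pigment epithelium, 4.48 for crystallin, 1.55 for lens fiber, 2.88 for corneal epithelium, 1.37 for keratocyte, 0.86 for trabecular meshwork, 0.31 for myelin and 0.74 for astrocyte genes. After quantile normalization they were 5.15 for crystallin, 2.06 for lens fiber and 0.27 for smooth muscle genes in iris. With the mean of all clusters of a gene, the fibrous matrix list had 1.08.

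Over only the members above the array median, which drops dim genes by construction, the medians were 3.50 for rod, 2.33 for cone, 0.80 for bipolar, 1.43 for ganglion cell, 1.29 for Müller glia, 1.33 for pigment epithelium, 1.75 for melanocyte, 0.77 for complement, 2.09 for keratocyte, 1.14 for fibrous matrix, 2.20 for myelin and 1.41 for astrocyte genes.

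Taking the difference from the highest other tissue, in place of the median of the others, can only lower a value. It gave 2.25 for rod, 1.47 for cone, 0.051 for bipolar, 0.17 for pigment epithelium, 0.093 for melanocyte, 5.01 for crystallin, 2.04 for lens fiber, 2.35 for corneal epithelium, 0.053 for fibrous matrix and 0.0020 for cartilage genes. It was -0.52 for corneal endothelium, -0.66 for ion transport, -1.38 for smooth muscle in iris and -0.29 for corneal dystrophy genes, whose medians had been positive but below the spread guide. The sign of the 10 medians above the guide turned, to -0.083 for amacrine and horizontal, -0.13 for ganglion cell, -0.73 for Müller glia, -0.085 for vascular endothelium, -0.70 for complement, -0.24 for keratocyte, -0.31 for trabecular meshwork, -0.17 for ciliary epithelium, -0.13 for myelin and -0.36 for astrocyte genes.

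Signal over background limits all of this. Near the array median a gene's fold depends on the pseudocount, and a difference of a dim gene was not detectable here; it is not shown to be absent.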

Other observations

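The tests of muscle cells in the trabecular meshwork and of the scale of the lens array were chosen only after their results were seen. The same holds for the test of ciliary epithelium as the source of contractile transcripts in the trabecular meshwork. The cadherin, cilium, synaptic, MHC class II, proteasome and ribosomal groups were picked after their values were seen. So were the olfactory receptor, the secretoglobin and gland, and the neutrophil groups, and all single genes in this part.

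Desmosomal cadherins, which hold epithelial cells together, were highest in cornea for 6 of 7 members, 4 of them enriched, with a median difference of 3.73 (log2), 3.65 after quantile normalization and 3.68 after median centring. DSC2 reached 667 there. Cilium genes, most of them tied to Bardet-Biedl or Joubert syndrome, were highest in retina for 10 of 13 members under all 3 scalings, with a median of 1.26. They included AHI1 (347), BBS7 (185), BBS9 (173), TMEM237 (145) and ARL6 (103), and RPGRIP1 (388), a photoreceptor cilium gene outside both syndromes. Genes of synaptic vesicle release were highest in retina for 15 of 30 members, 8 of them enriched, with a median of only 0.28, and included SYT1 at 800.4, RIMS2 at 573, SNAP25 at 502, SYP at 469 and CADPS at 245.

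MHC class II genes, which present antigens, were lowest in lens, retina and cornea. Their median was -1.54 in lens, -1.31 in retina and -1.07 in cornea, against 0.60 in RPE/choroid, 0.36 in trabecular meshwork and 0.26 in sclera, with the same signs under both other scalings; after quantile normalization sclera rose to 0.67, above RPE/choroid. CD74 fell from 287 in trabecular meshwork to 14.9 in lens and HLA-DRA from 445 in sclera to 19.9 in lens. Proteasome subunits were highest in lens for 16 of 29 members, and for 13 after quantile normalization. Their lens median of 0.57 fell to 0.24 after that scaling, below the 0.27 of trabecular meshwork, and they had a median of -0.50 in retina. Ribosomal proteins were highest in lens for 14 of 26 members, with a median of 0.49, and for 9 with a median of 0.27 after quantile normalization.

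Photoreceptor genes were found in the RPE/choroid library, which was the next tissue after retina for 15 of the 22 retina-enriched rod and cone genes. The scale of the arrays is argued against, because 14 of the 22 had RPE/choroid next after quantile normalization. Whole retina carried into the sample stays open. The 6 inner retinal genes had a median share of 13.7% of the retinal signal, above the upper quartile of 12.3% for rod and cone genes. Their quartiles of 11.4% and 20.9% overlap the rod and cone range. Both sets held only retina-enriched genes, a rule that leaves out genes with a high share. The inner set included NEFL, NEFM, NEFH and STMN2 of the ganglion cell list, with optic nerve head next after retina for NEFM and sclera for NEFH. Expression in RPE/choroid cells themselves, as a tissue difference, also stays open and was not tested.

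Contractile genes were high in the trabecular meshwork library. The scale of the arrays is argued against as the whole cause, because 8 of the 13 smooth muscle genes were highest there after quantile normalization. As deposited the count was 11, so a part played by the scale is not excluded. The ciliary epithelium list was lower in trabecular meshwork than in ciliary body, with a median of -0.34 (log2). Its bootstrap interval over genes was -0.62 to -0.054, and it lay below 0 under both other scalings. The smooth muscle list was higher in trabecular meshwork than in ciliary body, with a median of 0.83. Dilution cannot pass its source, so carried tissue with the make-up of the ciliary body library is argued against as the whole cause. Carried ciliary body tissue richer in contractile cells, or those cells without epithelium, cannot be decided on in this way. The epithelium list also marked ciliary body only weakly, with 6 of 15 members highest there. The interval runs over genes of 1 library per tissue and gives no spread between samples. The test set beforehand, a median of 0.012 for the epithelium list against all other tissues, decided nothing. A small contribution of ciliary epithelium is not excluded. Muscle cells in the dissected sample stay open, because the count of 11 of 13 members highest there restates the pattern and DES, a muscle filament gene at 1.09-fold over the median of the other tissues, lies near background. That the meshwork's own cells express these genes is a tissue difference that was not tested.

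Lens had 2.25 times as many enriched genes as the next tissue. After quantile normalization this ratio was 1.09, with 154 genes in lens and 142 in retina, under the 4-fold rule it was 1.54, and after median centring, which hardly moved the lens array, it was 2.26 with 262 genes in lens. The scale of the lens array and a real excess of lens genes cannot be told apart, since quantile normalization assumes equal distributions, which crystallin-rich lens RNA may not meet.

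OR4A16 was the only enriched gene among 225 olfactory receptors, at 2013 in lens and 11.8 to 38.6 elsewhere. IK was at 112 in iris and 491 to 1036 in the other tissues. ENO1 was at 24.0 in ciliary body and 882 in cornea, and EIF3L at 19.2 in ciliary body and 384 in lens. The highest tissue exceeded the lowest 22.4-fold for ENO1, 11.4-fold for EIF3L and 8.23-fold for IK. Whether tissue or measurement caused these ranges was not tested. SCGB1D2 was at 226 in lens and 0.0021 in trabecular meshwork. Of 15 secretoglobin and gland genes, 5 were highest in sclera, which had the highest mean (6.78), and 3 were enriched there, SCGB3A2, SLPI and PLA2G2A. The median difference of the group was only 0.105 in sclera, against 0.112 in RPE/choroid and 0.132 in optic nerve. Of 9 neutrophil genes, 2 were highest and enriched in RPE/choroid, S100A12 and S100A8, and 4 were highest in sclera. The mean was highest in RPE/choroid (6.79, against 6.13 in sclera). The median difference was 0.16 in RPE/choroid and 0.19 in sclera, both below the spread guide. MT1G was at 619 in lens and MT1L at 309 in iris. Among clusters that carried several gene symbols, 42 were enriched in lens, as were 43 with no symbol.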
